A study of Glycine max with 18 samples.

How the data were processed

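The samples were seeds of soybean, cultivar Asgrow A3237, 2.5 to 3 mm long, from plants grown at 22 °C with 16 h of light and 8 h of dark. Per the labels, seeds were fixed in ethanol and acetic acid, embedded in paraffin and sectioned at 8 µm, and 8 compartments were captured with a laser microdissection microscope. RNA of the captures was isolated with a PicoPure kit and whole seed RNA with a plant RNA reagent. From 2 ng of RNA, amplified RNA was made with RiboAmp OA, labelled with an ENZO kit and hybridized to the Affymetrix Soybean Genome Array, 18 arrays in 9 groups of 2. The deposited values are intensity, a linear signal per probe set, which the authors made with GCOS 1.3. The settings of that software and any background step are not stated. The 2% trimmed mean of the signals was 500 on every array, as measured in the deposited table, and 12 values were 0. The table held no detection calls.

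The labels do not state how many plants or seeds an array holds. The p-values therefore measure the spread between these samples alone, which can be partly technical, and captures of different compartments can come from the same seeds.

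Of 61170 probe sets, 37593 are for soybean, and the 23577 for other organisms and controls were left out of the tests. Signals under 50 were set to 50 and all were taken to log2. Soybean probe sets with a signal of at least 100 on at least 2 arrays were tested, 31955 in all. The lmFit and eBayes functions of limma 3.58.1 (with a variance trend) in R 4.3.3 fitted a mean for each of the 9 groups, and 14 contrasts of these means were tested. P-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. A fold is the ratio of geometric means, and SE is the moderated standard error of the log2 fold. Folds with lower-side arrays at the floor are lower bounds. If all lie there, named genes carry "at least" but list members do not. In 109 of 216 named results the mean of the lower side was under the 95th percentile of other-organism probe sets averaged over its arrays, and the sizes of such folds depend on background. A probe set was counted as highest in a compartment when it passed and was higher against each of the other 7. Where a group is left with 1 array, that array is assumed to vary as the other groups do.

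The probe table gave exactly 1 gene symbol for 8677 soybean probe sets and several for 370, and did not list 28546. Of 5703 genes with 1 symbol and a tested probe set, 1043 had a name other than a LOC number, and the named genes come from these. Each gene was read from the probe set with the highest mean log2 signal. Names in each compartment are the 12 largest rises with both arrays above all 14 arrays of the other compartments, and the 4 largest falls with both below. For embryo proper against suspensor and embryo against seed coat they are the 12 largest changes each way without overlap of arrays, and for the layer pairs and whole seed the 5 largest each way. Probe sets with a suffix for possible binding of related transcripts stand behind ACCC-2, ADR12, AS2, AT133, BBI-1, BZIP94, C4H, CAB3, CHI4A, CHR5, ERF5, F3H, GASA14, GASA33, GER2, GST3, GY1, H4, HSP23.9, HSP90A1, IFS2, KTI-3, LOX1.4, LOX3, LOX7, LOX9, MIPS4, NAC14, NOD33, OAS-TL3, PETC, PIP2-4, PIP2-6, PM3, PRP1, PRP2, PRP3, RCABETA, RPS6, SARK, SBP2, SGT2, SGT3, SODB, TEFS1, VPE2, WIN, WRKY16. Another probe set of the gene had the opposite sign for CYP93E1 in embryo proper, OAS-TL3 in endosperm, CYP98A2 and GBSSIa in endothelium, HIDH in inner integument, COL10 and NAC14 in outer integument, NAC14 in inner against outer integument and MYB138 in epidermis against outer integument. No genome coordinates were used.

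Gene lists were tested with camera in limma, with a preset correlation of 0.01 and, as an alternative, an estimated one. Lists needed at least 5 measured genes. There were 45 lists of name patterns written before the data were examined, as were the contrasts, thresholds, naming rule and all alternatives but 1. The tables held no gene descriptions, so the patterns were matched to symbols and synonyms, and PAP25 and SOYAP2 were removed as chance matches of spelling. Of these lists, 9 could be tested in the 14 contrasts (126 tests), which gave 11 calls, 0 of them with the estimated correlation. A further 34 lists of symbols were written after the annotation had been seen but ahead of any test of a gene. Of these, 28 could be tested (392 tests), with 61 calls and 4 with the estimated correlation. Benjamini-Hochberg adjustment ran over the lists and contrasts of each of these families. Members given as examples are among the 4 with the smallest p unless stated.

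The method was tested on simulated data, 3 runs with 200 changed of 31955 probe sets. Recovery of 2-fold, 4-fold and 8-fold changes was 22.9%, 83.6% and 100% in embryo proper against the other 7 (mean of 11.3 false calls). It was 19.9%, 83.1% and 100% in hilum (6.33) and 7.96%, 57.2% and 88.9% in embryo proper against suspensor (5.67). The real contrasts had at least 4195 passing, so these rates need not hold there. Alternatives were quantile normalization, floors of 25 and 100, no floor with log2 of the signal plus 1, no filter, a filter at 300, eBayes without the trend, a replicate block, the 16 captured arrays alone, each array left out, all probe sets of a gene in the list tests, and the estimated correlation. Leaving out the 3 high-background arrays was added after the data were seen.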

Results

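Gene activity was measured in 8 compartments captured by laser from soybean seeds with cotyledon-stage embryos, and in whole seed, with 2 arrays for each of the 9 groups. The compartments were the embryo proper, the suspensor (the stalk that joins the embryo to the seed coat), the endosperm, and 5 parts of the seed coat: endothelium, inner integument, outer integument, epidermis and hilum. On each array 56.7% to 67.4% of the 37593 soybean probe sets had a signal of at least 100. The Pearson correlation of the log2 signals of the 2 arrays of a group, taken across genes, ran from 0.935 in suspensor to 0.975 in whole seed. Each group correlated less with its nearest other group, the closest pair being endothelium and inner integument (0.917). Genes are not independent replicates, so these correlations describe the arrays only. The 95th percentile of the signals of probe sets for other organisms was 213 on epidermis array 2, 207 on inner integument array 1 and 197 on outer integument array 1. It was 134, 135 and 152 on the other array of each pair, 184 and 216 on the hilum arrays, and 189 and 160.1 on the suspensor arrays. Those first 3 arrays are called the high-background arrays here. They were singled out after the data were seen. The small number of arrays limits the precision of every value.

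Each compartment held probe sets whose signal was higher than in each of the other 7, and the suspensor held the most, 819. Endosperm followed with 603, embryo proper with 499, inner integument with 445 and outer integument with 441. Hilum had 263, endothelium 139 and epidermis 110. Leaving out 1 array moved several of these counts by more than 1.5 times. Embryo proper then had 307 without its array 1 and 303 without its array 2, and endosperm had 297 and 361. Endothelium had 69 and 75 without its own arrays 1 and 2, and 80 without inner integument array 1. Inner integument had 266 and 248 without its own arrays 1 and 2, and 277 without endothelium array 2. Epidermis had 64 without its array 2, hilum 150 without its array 2 and outer integument 252 without its array 1. Without the 3 high-background arrays the counts were 75 in endothelium, 65 in epidermis, 240 in inner integument and 215 in outer integument. The hilum count was 160 with the floor of 25, 463 with the floor of 100 and 97 with none. Without a floor, embryo proper had 325, epidermis 52 and outer integument 286.

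**Figure D1:**
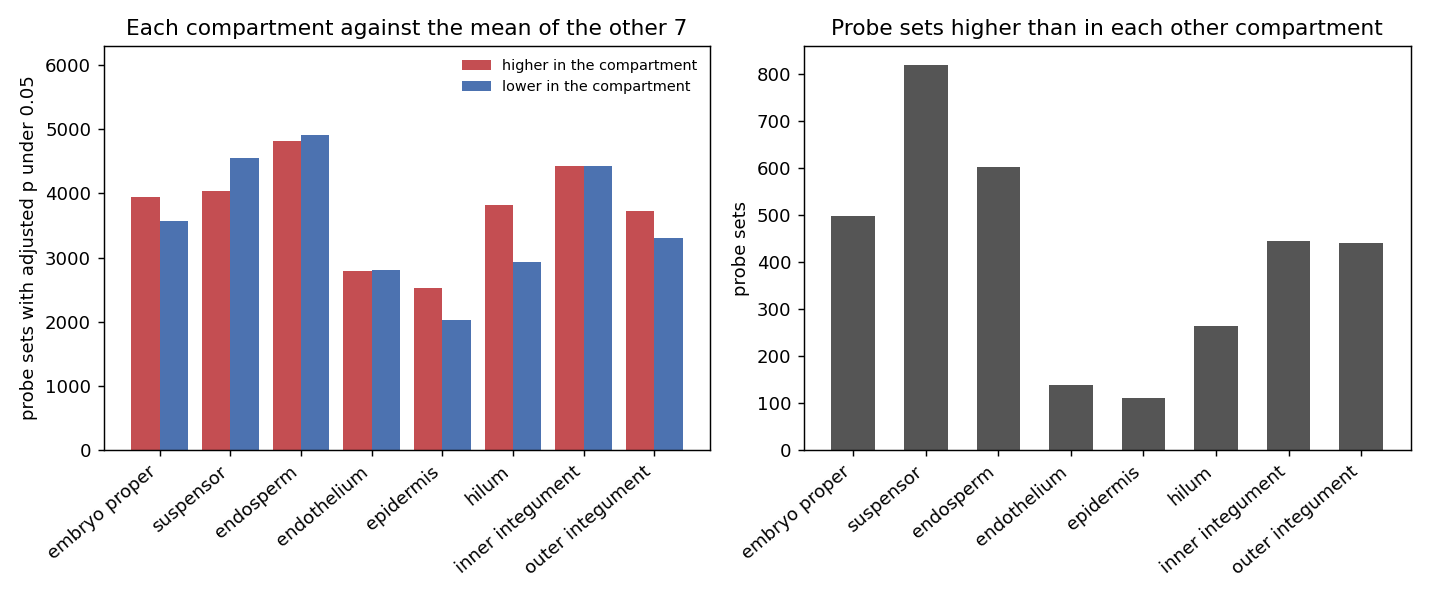
Bars give numbers of probe sets for each of the 8 captured compartments, on the left those with adjusted p under 0.05 that were higher or lower than the mean of the other 7, and on the right those higher than in each other compartment. Endosperm has the most passing probe sets on the left (4824 higher and 4910 lower), and suspensor the tallest bar on the right (819).

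The first set of comparisons asked which genes were more or less active in each compartment than in the mean of the other 7 (2 arrays against 14). In the embryo proper, GmYABBY11 (symbol LOC100500091), of the YABBY transcription factor family that acts in lateral organs, was 92.1-fold (log2 fold 6.52 ± 0.36 SE) higher than elsewhere. IF7GT, an isoflavone glucosyltransferase, was 63.3-fold (log2 fold 5.98 ± 0.34 SE) higher, and A1, listed with the storage proteins, 46.5-fold (log2 fold 5.54 ± 0.51 SE) higher. KTI3, a Kunitz trypsin inhibitor, was 31.9-fold higher and PHANa, a MYB factor of the PHANTASTICA type, 23.1-fold higher. The other genes with the largest rises were H1, GSTU3, GSTF7, HSF, GmCSyGT3, CYP93E1 and SODB, from 19.9 to 36.1-fold higher. Of these, GSTU3 is LOC547576 in the tables, HSF is LOC100782841 and GmCSyGT3 is LOC100802222. AGL1L, a MADS-box factor, had both embryo proper arrays under the floor and was at least 81.9-fold lower than elsewhere. The proline-rich cell wall proteins PRP3 (41.7-fold) and PRP1 (29.7-fold) and the MADS-box factor SEP1 (24.4-fold) were also lower.

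By gene group, of 9 photosynthesis genes in embryo proper, 7 were higher, 0 lower and 2 neither (adjusted p = 0.00258, and 0.168 with an estimated correlation), led by CAB3 (7.44-fold), RCA14 (2.91-fold), ELIP (2.59-fold) and PETC (3.79-fold). Of 9 genes of plastid fatty acid synthesis, 6 were higher, 0 lower and 3 neither (adjusted p = 0.0111, and 0.314 with an estimated correlation), among them the acetyl-CoA carboxylase subunit genes ACCB-2 (5.56-fold), ACCC-2 (3.29-fold) and ACCC-3 (2.62-fold). Seed lectins and protease inhibitors counted 6 genes, of which 4 were higher, 0 lower and 2 neither (adjusted p = 0.0364, and 0.427 with an estimated correlation), with KTI3 (31.9-fold) and KTI-3 (10.4-fold) in front. The lectin and inhibitor list lost its call (adjusted p in parentheses) with a floor of 25 (0.0534), without a floor (0.0676), without the filter (0.0651) and without the 3 high-background arrays (0.0535). MADS-box factors went the other way: of 6, 0 were higher, 5 lower and 1 neither (adjusted p = 0.000260, and 0.119 with an estimated correlation), including MADS28 (37.6-fold) and SEP1 (24.4-fold). Of 5 cell wall proteins, 0 were higher, 4 lower and 1 neither (adjusted p = 0.00278, and 0.173 with an estimated correlation). The largest of these falls was that of SCB1, 29.9-fold without embryo proper array 1 and 126-fold without array 2, against 61.4-fold with both. NAC factors, a list fixed in advance, numbered 18, of which 0 were higher, 10 lower and 8 neither (adjusted p = 0.00243, and 0.139 with an estimated correlation), and 0 higher and 11 lower when adjusted over the list alone. NAC2 was 8.58-fold and GmNAC109 (LOC100170714) 4.23-fold lower. The lectins and inhibitors passing numbered 2 higher without embryo proper array 2, and fatty acid genes passing numbered 1 lower without epidermis array 1. In all, 7514 of 31955 probe sets passed, 3938 higher and 3576 lower. Leaving out embryo proper array 1 gave 4162 and leaving out array 2 gave 3964.

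The suspensor stood apart by genes of late embryogenesis and seed maturation. MP2 was 591-fold (log2 fold 9.21 ± 0.37 SE) higher than in the mean of the other 7 compartments, PM25 554-fold (log2 fold 9.11 ± 0.34 SE), PM32 360.3-fold (log2 fold 8.49 ± 0.40 SE) and PM9 270.2-fold (log2 fold 8.08 ± 0.36 SE). Of 29 measured genes of this list, 26 were higher, 1 lower and 2 neither (adjusted p = 6.56e-17, and 0.0105 with an estimated correlation), a call that held with the estimated correlation. LEA-2, named after its values were seen, was the member that fell, by 8.99-fold. LOX3, a lipoxygenase, was 393-fold higher, PARP3 338-fold, and ODC2, an ornithine decarboxylase of polyamine synthesis, 99.8-fold. The other named rises were PM3 (246-fold), PM12 (224-fold), P89 (117-fold), PGMPM10 (104-fold) and AT133 (96.8-fold). The aquaporins PIP2-1 and PIP2-6 were 51.5-fold and 28.5-fold lower. GDH1, a glutamate dehydrogenase with both suspensor arrays under the floor, was at least 21.2-fold lower, and MYB134 18.2-fold lower. The fold varied with the array left out for PIP2-6, 17.51-fold without suspensor array 1 and 46.2-fold without array 2.

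Of 45 WRKY factors in suspensor, a list fixed in advance, 17 were higher, 3 lower and 25 neither (adjusted p = 0.00766, and 0.469 with an estimated correlation), and 17 higher and 3 lower when adjusted over the list alone. WRKY16 was 28.1-fold, WRKY51 25.3-fold, WRKY11 (LOC100170685) 19.4-fold and WRKY54 10.7-fold higher. Of the 6 MADS-box factors, 0 were higher, 5 lower and 1 neither (adjusted p = 0.00157, and 0.169 with an estimated correlation), AGL1L by 14.5-fold and AGL3L by 4.56-fold. WRKY factors passing numbered 1 lower without suspensor array 1. In all, 8604 of 31955 probe sets passed, 4046 higher and 4558 lower.

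The embryo proper and the suspensor, the 2 parts of the embryo, were also compared directly (2 arrays against 2). Genes of maturation were again on the suspensor side: PM32 was 398-fold (log2 fold -8.64 ± 0.53 SE) lower in embryo proper and PM25 209-fold (log2 fold -7.71 ± 0.45 SE) lower. The embryo proper signal of PM32, 77.8, lay under the 95th percentile of other-organism probe sets on those arrays (133 and 143), so the size of its fold depends on background. The lower side lay under that level, averaged over its arrays, for IF7GT, GmYABBY11, PHANa, LRK1, CDPK, ALDH2B4, HSF, GmCRY1c1, GSTU37, PIP2-8, PGIP, H4, PRP2, PIP1-1, SCAM-4 and GSTU21 as well. Of 29 genes of this list, 1 was higher, 21 lower and 7 neither (adjusted p = 2.89e-09, and 0.0284 with an estimated correlation), and that call too held with the estimated correlation. WRKY51 was 186-fold lower in embryo proper, CHI2-A, a chalcone isomerase, 165-fold, PRP2 137-fold and the aquaporin PIP1-1 131-fold. PGIP, named as a polygalacturonase inhibitor, was at least 209-fold lower. H4, PM9, SCAM-4, LOX3 and GSTU21 completed the 12 largest falls, of which SCAM-4 fell 121-fold, LOX3 121-fold and GSTU21 (LOC547581) 115-fold. On the embryo proper side, IF7GT was 125-fold (log2 fold 6.96 ± 0.45 SE) higher, PHANa 104-fold (log2 fold 6.70 ± 0.37 SE) higher and PIP2-1 87.5-fold (log2 fold 6.45 ± 0.26 SE) higher. Both suspensor arrays lay under the floor for GmYABBY11 (at least 108-fold higher in embryo proper), LRK1 (at least 62.4-fold), ALDH2B4 (at least 33.98-fold) and the cryptochrome GmCRY1c1 (LOC100786551, at least 30.9-fold). HSF and GSTU37 were 33.8-fold and 29.7-fold higher.

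Several of the largest folds between embryo proper and suspensor varied by more than 1.5 times with the array left out, and passed either way. These were H4, 340.1-fold without embryo proper array 1 and 94.5-fold without array 2 (lower in embryo proper, 179-fold with all), PM9, 103-fold without embryo proper array 1 and 249-fold without array 2 (lower, 159.7-fold), CDPK, 61.9-fold without suspensor array 1 and 21.8-fold without array 2 (higher, 36.7-fold), PIP2-8, 77.6-fold without suspensor array 1 and 10.8-fold without array 2 (higher, 28.97-fold), and KTI-3, 12.4-fold without suspensor array 1 and 55.6-fold without array 2 (higher, 26.3-fold). Of 9 photosynthesis genes, 8 were higher, 0 lower and 1 neither (adjusted p = 0.00543, and 0.173 with an estimated correlation), RCABETA by 16.9-fold and CAB3 by 10.2-fold. Cell wall proteins, 5 in number, had mostly lower signals in embryo proper: 1 was higher, 4 lower and 0 neither (adjusted p = 0.0437, and 0.314 with an estimated correlation), PRP3 by 111-fold. The call of the cell wall list was lost (adjusted p in parentheses) with a floor of 100 (0.0720), without the filter (0.0651), with the filter at 300 (0.0573) and without the 3 high-background arrays (0.0653). The member higher in embryo proper, SBPRP, lost its call (adjusted p in parentheses) without the filter (0.103), without the variance trend (0.0771), with the captured arrays alone (0.0528), without the 3 high-background arrays (0.0866), without embryo proper array 1 (0.137), without embryo proper array 2 (0.121), without suspensor array 1 (0.221), without whole seed array 1 (0.0513) and without whole seed array 2 (0.0513). Cell wall proteins passing numbered 0 higher without embryo proper array 1 or 2, suspensor array 1 or whole seed array 1 or 2. Of 45 WRKY factors, 1 was higher, 19 lower and 25 neither (adjusted p = 0.00243, and 0.420 with an estimated correlation), and 1 higher and 19 lower when adjusted over the list alone, with WRKY54 55.7-fold and WRKY16 40.3-fold lower. Of 18 NAC factors, 0 were higher, 11 lower and 7 neither (adjusted p = 0.00243, and 0.139 with an estimated correlation), and 0 higher and 11 lower when adjusted over the list alone, with NAC69 77.7-fold and NAC6 24.2-fold lower. WRKY factors passing numbered 3 higher without suspensor array 1. For the other lists, NAC factors passing numbered 7 lower without embryo proper array 2, photosynthesis genes passing numbered 1 lower without suspensor array 2, and 5 higher without embryo proper array 2, and maturation genes passing numbered 2 higher without epidermis array 1 or 2. In all, 7867 of 31955 probe sets passed, 4129 higher and 3738 lower.

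**Figure D2:**
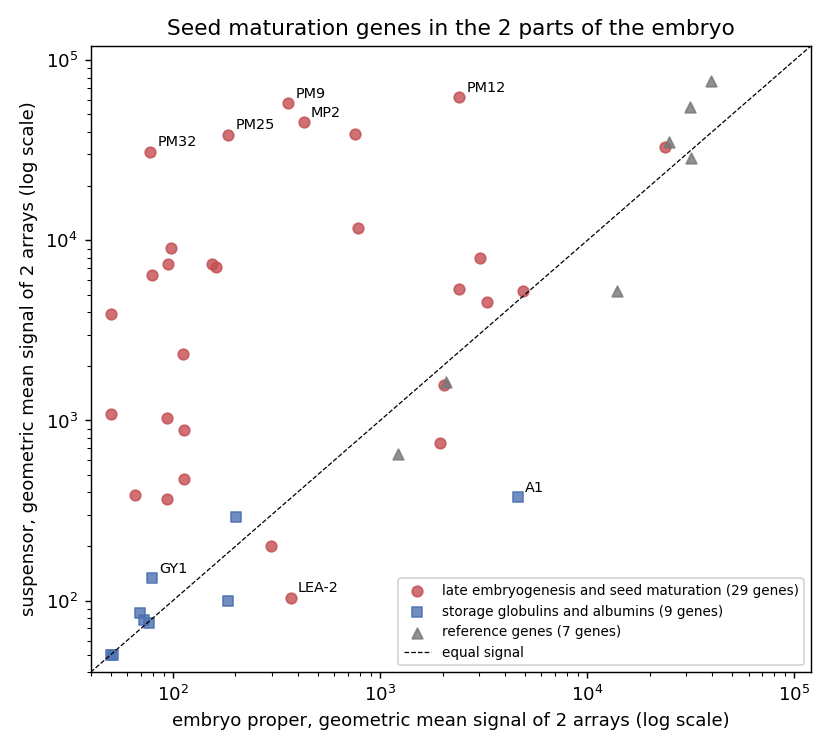
Each symbol is a gene, placed by the geometric mean signal of the 2 embryo proper arrays (horizontal axis, log scale) and of the 2 suspensor arrays (vertical axis, log scale), for 29 maturation genes, 9 storage protein genes and 7 reference genes, with a dashed line of equal signal. Of the 29 maturation genes 25 lie above the line, PM32 at 77.8 against 30980.5, whereas the storage gene A1 lies below it at 4629.8 against 374.

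In the endosperm, CYSP2, a cysteine protease, was 24.9-fold (log2 fold 4.64 ± 0.38 SE) higher than in the mean of the other 7 compartments and LAX11, of the auxin influx carrier family, 15.7-fold (log2 fold 3.97 ± 0.27 SE) higher. ERF5 was 11.5-fold higher and OAS-TL2, of cysteine synthesis, 11.2-fold. The other named rises were CDPK-BETA (9.24-fold), PIP2-10 (8.61-fold), HSP23.9 (8.31-fold), SACPD-C (6.85-fold), CLV1A (6.46-fold), EXP2 (5.82-fold), HSP90A1 (5.8-fold) and OAS-TL3 (5.24-fold). CLV1A no longer passed without endosperm array 1 (adjusted p = 0.0916). GASA14, a gibberellin-responsive gene, was 54.5-fold (log2 fold -5.77 ± 0.21 SE) lower. AOC3, an allene oxide cyclase of jasmonate synthesis, was 39.3-fold lower, the aquaporin PIP2-4 33.4-fold and RCA14, a rubisco activase, 29.002-fold.

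Most of the gene groups that differed in endosperm were lower there. Of 15 jasmonate and lipoxygenase genes, 1 was higher, 10 lower and 4 neither (adjusted p = 0.000260, and 0.0596 with an estimated correlation), AOC4 by 18.7-fold and VLXB by 9.80-fold. Early flavonoid genes numbered 9, and 0 were higher, 8 lower and 1 neither (adjusted p = 0.00258, and 0.169 with an estimated correlation), CHI4A by 22.4-fold and F3H by 3.73-fold. Of 9 photosynthesis genes, 0 were higher, 6 lower and 3 neither (adjusted p = 0.00201, and 0.152 with an estimated correlation), CAB3 by 22.2-fold. Of 20 aquaporins, 2 were higher, 13 lower and 5 neither (adjusted p = 0.0134, and 0.188 with an estimated correlation), PIP1-1 by 9.86-fold and PIP2-9 by 5.63-fold. Of 6 MADS-box factors, 0 were higher, 5 lower and 1 neither (adjusted p = 0.00129, and 0.169 with an estimated correlation), MADS28 by 26.6-fold. The 5 peroxidases divided so that 0 were higher, 4 lower and 1 neither (adjusted p = 0.0219, and 0.349 with an estimated correlation), PRX2B by 17.2-fold and PRX2 by 13.5-fold. Among 5 cell wall proteins, 0 were higher, 5 lower and 0 neither (adjusted p = 0.0182, and 0.272 with an estimated correlation), PRP3 by 11.8-fold. Of 18 genes of gibberellin turnover and response, fixed in advance, 0 were higher, 10 lower and 8 neither (adjusted p = 0.00279, and 0.397 with an estimated correlation), and 1 higher and 10 lower when adjusted over the list alone, with GASA27 18.5-fold lower. Ribosomal proteins and 14-3-3 proteins were on the higher side: of 5 and 8 genes, 4 and 5 were higher and 0 lower. Their adjusted p were 0.00931 and 0.00404, or adjusted p = 0.260 and adjusted p = 0.273 with an estimated correlation, with RPS6 2.36-fold and SGF14f 4.94-fold higher. Jasmonate genes passing numbered 0 higher without endosperm array 1 or 2, and gibberellin genes passing numbered 1 higher without suspensor array 1 or 2 or epidermis array 2. Early flavonoid genes passing numbered 4 lower without endosperm array 1, and peroxidases passing numbered 2 lower without endosperm array 1, and aquaporins passing numbered 8 lower without endosperm array 1, and cell wall proteins passing numbered 3 lower without endosperm array 2. In all, 9734 of 31955 probe sets passed, 4824 higher and 4910 lower. Leaving out endosperm array 1 gave 5595 and leaving out array 2 gave 6288.

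In the endothelium, the innermost layer of the seed coat, GA2OX6, a gibberellin 2-oxidase of gibberellin inactivation, was 55.2-fold (log2 fold 5.79 ± 0.32 SE) higher than in the mean of the other 7 compartments. The receptor-like kinase gene SARK was 59.4-fold (log2 fold 5.89 ± 0.36 SE) higher, CYP84A16 (LOC100793538), of the ferulate 5-hydroxylase family, 52.5-fold (log2 fold 5.72 ± 0.40 SE), and AUX22, of the Aux/IAA family, 49.0-fold (log2 fold 5.61 ± 0.22 SE). WRKY54 was 17.7-fold higher, and the remaining named rises were HPT1 (9.96-fold), GAD (9.86-fold), 4CL3 (9.79-fold), ALDH2C8 (9.15-fold), GASA9 (9.12-fold), GS-2 (8.65-fold) and CYP98A2 (7.83-fold). GAD is LOC547724 in the tables. The starch synthase GBSSIa was 10.05-fold lower, CP3 7.57-fold, the zeaxanthin epoxidase ZEP 6.61-fold and WRKY16 5.44-fold. Of 9 phenylpropanoid and lignin genes, 6 were higher, 0 lower and 3 neither (adjusted p = 0.00241, and 0.108 with an estimated correlation), 4CL1 by 17.3-fold, C4H by 2.31-fold and CYP98A2 by 7.83-fold. Maturation genes numbered 29, of which 1 was higher, 16 lower and 12 neither (adjusted p = 3.22e-05, and 0.0885 with an estimated correlation), PM12 by 10.8-fold and PM34 by 6.76-fold. The mean of the other 7 holds the suspensor, where most of these genes had far higher signals. PM12 had 62295 there, 67.8 in endothelium and at most 345 in any seed coat compartment. Lower maturation genes, here and in the other seed coat compartments, thus need not mean a fall particular to that compartment. Proanthocyanidin and anthocyanin genes counted 6, of which 0 were higher, 3 lower and 3 neither (adjusted p = 0.0364, and 0.283 with an estimated correlation), with ANR1 lower (1.82-fold without endothelium array 1 and 6.85-fold without array 2, the first with adjusted p = 0.107). The proanthocyanidin list lost its call (adjusted p in parentheses) without the 3 high-background arrays (0.0535). Maturation genes passing numbered 9 lower without endothelium array 1 and 10 lower without endothelium array 2, and 0 higher without endothelium array 1, and proanthocyanidin genes passing numbered 0 lower without endothelium array 1. Phenylpropanoid genes passing numbered 1 lower without outer integument array 1 or 2. In all, 5611 of 31955 probe sets passed, 2799 higher and 2812 lower. Leaving out endothelium array 1 gave 3083 and leaving out array 2 gave 3330.

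In the epidermis of the seed coat, SSH2 was 65.7-fold (log2 fold 6.04 ± 0.39 SE) higher than in the mean of the other 7 compartments, and DFR1, a dihydroflavonol reductase, 58.7-fold (log2 fold 5.88 ± 0.33 SE) higher. GASA33 was 30.0-fold higher. The other named rises were BZIP48 (12.9-fold), GmGSTU2 (11.1-fold), CRK5 (10.5-fold), LBD23 (8.55-fold), EDS1-2 (5.79-fold), COL19 (5.16-fold), FLS1 (4.35-fold), PK1b (3.76-fold) and WIN (3.58-fold), in which GmGSTU2 is LOC100306119, COL19 is LOC100793296 and PK1b is LOC100809679. AUX22 was 21.1-fold (log2 fold -4.40 ± 0.22 SE) lower, CCR, of lignin synthesis, 15.1-fold, MYB138 11.6-fold and HSF-35 8.12-fold. Single arrays moved 3 of these folds: BZIP48, 19.7-fold without epidermis array 1 and 8.46-fold without array 2, CCR, 32.5-fold without epidermis array 1 and 7.03-fold without array 2, and MYB138, 30.6-fold without epidermis array 1 and 4.43-fold without array 2. Without epidermis array 2, COL19 and WIN did not pass (adjusted p = 0.0593 and 0.156), nor did they without the 3 high-background arrays (adjusted p = 0.0773 and 0.159). FLS1 did not pass without array 1 (adjusted p = 0.0861) or without a floor (adjusted p = 0.0530).

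Of 6 proanthocyanidin and anthocyanin genes in epidermis, 4 were higher, 0 lower and 2 neither (adjusted p = 0.000260, and 0.113 with an estimated correlation), ANS2 by 46.9-fold, ANR1 by 31.2-fold and DFR2 by 9.27-fold. Of 9 early flavonoid genes, 5 were higher, 1 lower and 3 neither (adjusted p = 0.00470, and 0.173 with an estimated correlation), F3H by 12.4-fold, CHI4A by 10.3-fold and CHI2-A by 10.2-fold. All 5 cell wall proteins passed, and 5 were higher, 0 lower and 0 neither (adjusted p = 0.000381, and 0.119 with an estimated correlation), PRP1 by 28.6-fold and PRP3 by 9.34-fold. Of 6 MADS-box factors, 3 were higher, 0 lower and 3 neither (adjusted p = 0.0197, and 0.275 with an estimated correlation), MADS28 by 12.2-fold and AGL1L by 5.32-fold. Of 29 maturation genes, 0 were higher, 8 lower and 21 neither (adjusted p = 0.000483, and 0.113 with an estimated correlation), MP2 by 4.04-fold. MP2 lay at the floor of 50 in each of the 5 seed coat compartments. Its fall follows mainly from its signals in the embryo, 45230 in suspensor and 427 in embryo proper. Maturation genes passing numbered 4 lower without epidermis array 2, early flavonoid genes passing numbered 0 lower without epidermis array 1 or 2, and proanthocyanidin genes passing numbered 1 lower without epidermis array 2. In all, 4554 of 31955 probe sets passed, 2525 higher and 2029 lower. The count was 2277 without epidermis array 2, the array with the higher background, and 2208 without the 3 high-background arrays.

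The hilum, where the seed joins the funiculus, had the highest signals of several proanthocyanidin genes. NMH7, a MADS-box factor, was 148-fold (log2 fold 7.20 ± 0.33 SE) higher than in the mean of the other 7 compartments, ANR1, the anthocyanidin reductase, 87.8-fold (log2 fold 6.46 ± 0.34 SE) and LAR1, the leucoanthocyanidin reductase, 42.4-fold (log2 fold 5.40 ± 0.45 SE). GASA6 was 68.0-fold higher, and CHS8, a chalcone synthase, 47.1-fold. The MYB factors MYB11, MYB172 and MYB73 were 31.6-fold, 29.6-fold and 28.4-fold higher. HIDH, of isoflavone synthesis, was 21.4-fold higher, 4CL4 20.9-fold and CHI4A 15.7-fold. MYB184 was 13.6-fold higher, a value that varied with the array left out (24.2-fold without hilum array 1 and 7.64-fold without array 2). SC-04 was 50.5-fold (log2 fold -5.66 ± 0.43 SE) lower, SC-03 31.5-fold and GDH2 17.9-fold, and PDH, with both hilum arrays under the floor, at least 24.1-fold lower.

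Of 6 proanthocyanidin and anthocyanin genes in hilum, 5 were higher, 0 lower and 1 neither (adjusted p = 3.95e-05, and 0.0944 with an estimated correlation), ANS2 by 58.2-fold and DFR1 by 34.1-fold. Of 9 early flavonoid genes, 5 were higher, 2 lower and 2 neither (adjusted p = 0.0179, and 0.260 with an estimated correlation), F3H by 12.8-fold and CHI2-A by 9.58-fold. MADS-box factors, 6 in number, rose in most cases: 5 were higher, 0 lower and 1 neither (adjusted p = 5.78e-05, and 0.109 with an estimated correlation), AGL1L by 9.83-fold and MADS28 by 9.58-fold. Of 20 aquaporins, 9 were higher, 3 lower and 8 neither (adjusted p = 0.0341, and 0.260 with an estimated correlation), PIP2-4 by 16.0-fold and PIP1-1 by 14.7-fold. The call of the aquaporin list was lost (adjusted p in parentheses) with the filter at 300 (0.0682). Maturation genes numbered 29, of which 0 were higher, 13 lower and 16 neither (adjusted p = 0.000556, and 0.113 with an estimated correlation), PM12 by 15.4-fold and PM34 by 7.37-fold. Maturation genes passing numbered 6 lower without hilum array 1 and 7 lower without hilum array 2, and 1 higher without endothelium array 1, and early flavonoid genes passing numbered 0 lower without hilum array 2, and aquaporins passing numbered 1 lower without hilum array 2, and 5 higher without hilum array 2. Proanthocyanidin genes passing numbered 1 lower without epidermis array 1. In all, 6757 of 31955 probe sets passed, 3820 higher and 2937 lower. The signals of other-organism probe sets were among the highest on the hilum arrays (95th percentiles 184 and 216). The count was 4112 without hilum array 1 and 3522 without array 2.

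**Figure D3:**
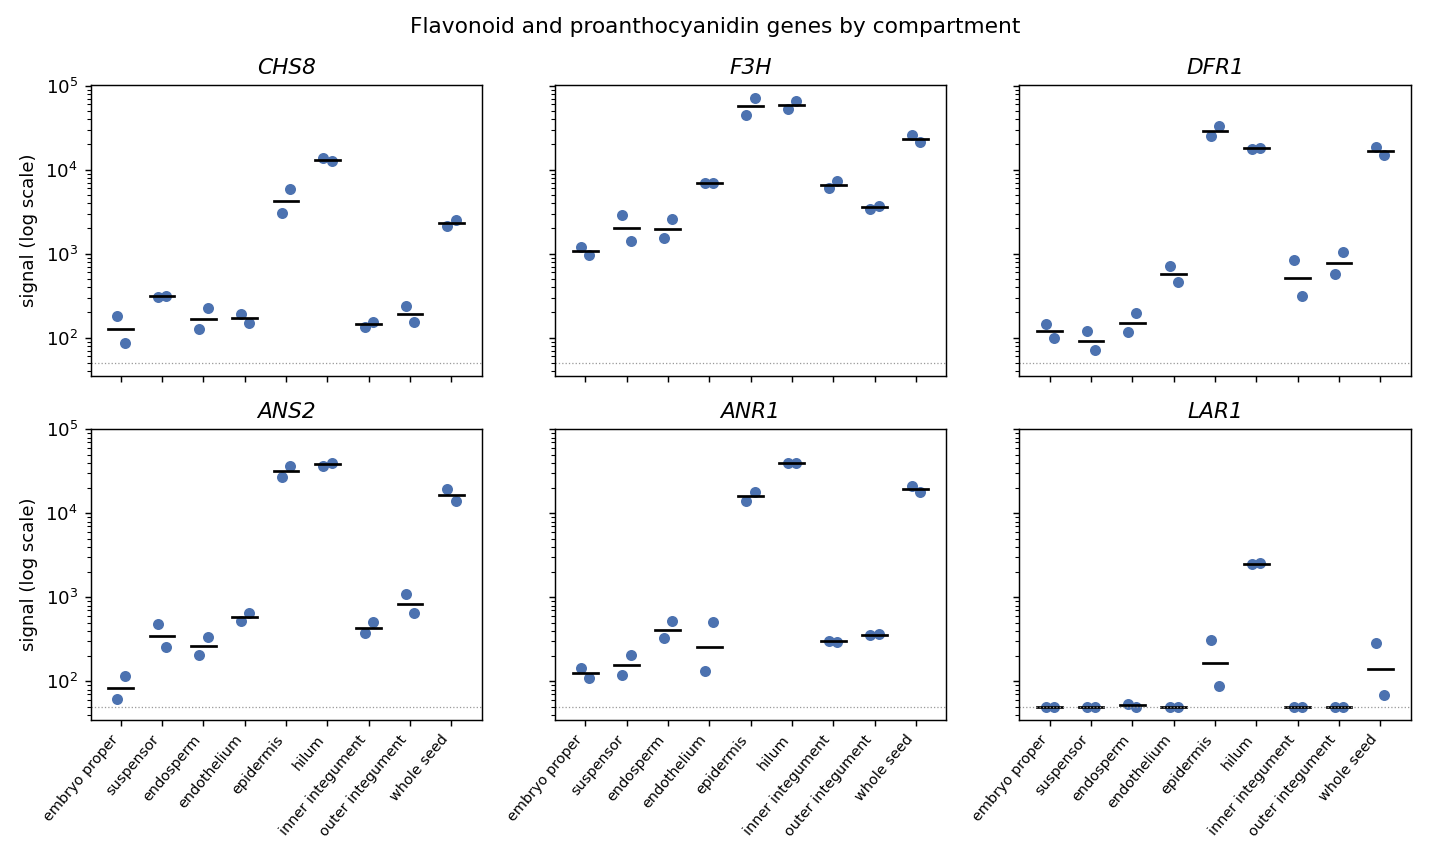
Signals (log scale) of 6 flavonoid and proanthocyanidin genes in the 9 groups, where each point is an array (values under 50 are drawn at 50), each black line is the geometric mean of 2 arrays and the dotted line is the floor of 50. ANR1 has a mean of 39308 in hilum and 15911 in epidermis and at most 414 in the other captured compartments, and LAR1 has 2526 in hilum.

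In the inner integument, NOD33 was 73.2-fold (log2 fold 6.19 ± 0.38 SE) higher than in the mean of the other 7 compartments, SGT3 (LOC732565) 60.6-fold (log2 fold 5.92 ± 0.38 SE) and N6L 53.6-fold (log2 fold 5.75 ± 0.51 SE). The sugar transporter genes SWEET13 and SWEET34 were 46.9-fold and 20.1-fold higher. SEOE, a sieve element occlusion gene, was 35.8-fold higher, BBI-1, a Bowman-Birk inhibitor, 34.8-fold and GS1-GAMMA, a glutamine synthetase, 21.7-fold. SABATH1 (22.4-fold), VPE2 (21.8-fold) and ALDH10A2 (19.3-fold) were also higher, and so was GST3 at 25.98-fold (49.5-fold without inner integument array 1 and 13.6-fold without array 2). HIDH was 30.5-fold (log2 fold -4.93 ± 0.26 SE) lower, WRKY11 17.2-fold, ACCB-2 13.5-fold and WRKY14 6.32-fold.

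Of 8 genes of sugar transport and cleavage in inner integument, a list fixed in advance, 6 were higher, 0 lower and 2 neither (adjusted p = 0.00243, and 0.356 with an estimated correlation), and 7 higher and 0 lower when adjusted over the list alone, with SWEET24 28.7-fold higher. Of 6 MADS-box factors, 5 were higher, 0 lower and 1 neither (adjusted p = 0.0197, and 0.275 with an estimated correlation), AGL1L by 6.48-fold and SEP1 by 5.17-fold. Ribosomal proteins counted 5, of which 0 were higher, 4 lower and 1 neither (adjusted p = 0.0111, and 0.260 with an estimated correlation), RPL2 by 2.55-fold. Of 29 maturation genes, 1 was higher, 11 lower and 17 neither (adjusted p = 0.0214, and 0.260 with an estimated correlation), PM29 by 6.30-fold, whereas LEA-2 was 5.84-fold higher. Of 9 early flavonoid genes, 0 were higher, 6 lower and 3 neither (adjusted p = 0.0477, and 0.292 with an estimated correlation), CHI2-A by 5.05-fold. The MADS-box list lost its call (adjusted p in parentheses) without the 3 high-background arrays (0.0597). That of the early flavonoid list was lost with a floor of 25 (0.0503), with a floor of 100 (0.0632), without a floor (0.0598), with the filter at 300 (0.0871), with the captured arrays alone (0.0550) and without the 3 high-background arrays (0.0835), and that of the maturation list with a floor of 25 (0.0862) and without a floor (0.168). Maturation genes passing numbered 7 lower without inner integument array 2, and early flavonoid genes passing numbered 3 lower without inner integument array 1 or 2. In all, 8867 of 31955 probe sets passed, 4435 higher and 4432 lower. The count was 5744 without inner integument array 1, the array with the higher background, and 5875 without the 3 high-background arrays.

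In the outer integument, the lipoxygenase genes LOX1.4 (LOC547835) and LOX7 were 75.5-fold (log2 fold 6.24 ± 0.24 SE) and 55.3-fold (log2 fold 5.79 ± 0.35 SE) higher than in the mean of the other 7 compartments, and IFR1, an isoflavone reductase, 69.3-fold (log2 fold 6.11 ± 0.43 SE) higher. SWEET24, a sugar transporter, was 53.6-fold (log2 fold 5.74 ± 0.32 SE) higher. The proline-rich protein gene SBPRP was 49.8-fold higher, the cytokinin oxidase CKX3 42.4-fold and NRT1-3, of the nitrate transporter family, 23.1-fold. The other named rises were Rsv4 (38.0-fold), N-26 (36.2-fold), GER10 (29.5-fold) and LOX9 (23.3-fold), Rsv4 being LOC100812666, and SSTP-1 at 38.7-fold (23.6-fold without outer integument array 1 and 63.3-fold without array 2). SODB, NAC14, COL10 and LAX11 were lower, by 14.3-fold, 11.7-fold, 6.64-fold and 5.63-fold.

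Of 15 jasmonate and lipoxygenase genes in outer integument, 11 were higher, 1 lower and 3 neither (adjusted p = 8.97e-06, and 0.0284 with an estimated correlation), AOC3 by 8.11-fold, VLXB by 11.8-fold and AOC4 by 9.84-fold. This call held with the estimated correlation. Of 9 phenylpropanoid and lignin genes, 1 was higher, 6 lower and 2 neither (adjusted p = 0.00285, and 0.109 with an estimated correlation), C4H by 4.53-fold and 4CL1 by 5.8-fold. Of 9 early flavonoid genes, 1 was higher, 6 lower and 2 neither (adjusted p = 0.0279, and 0.273 with an estimated correlation), CHI2-A by 3.99-fold. Genes of amino acid and nitrogen use numbered 18, of which 7 were higher, 1 lower and 10 neither (adjusted p = 0.0309, and 0.283 with an estimated correlation), NRT1-3 and ASP1 being the foremost rises, ASP1 by 10.7-fold. Of 20 aquaporins, 8 were higher, 3 lower and 9 neither (adjusted p = 0.0341, and 0.260 with an estimated correlation), PIP2-8 by 13.6-fold and PIP2-9 by 9.14-fold. MADS-box factors counted 6, and 4 were higher, 0 lower and 2 neither (adjusted p = 0.0163, and 0.273 with an estimated correlation), AGL1L by 11.4-fold. Maturation genes numbered 29, of which 2 were higher, 15 lower and 12 neither (adjusted p = 0.000909, and 0.119 with an estimated correlation), PM12 by 15.4-fold. The call of the aquaporin list was lost (adjusted p in parentheses) with a floor of 100 (0.0905), without the filter (0.0515) and without the 3 high-background arrays (0.0907). That of the MADS-box list was lost without the 3 high-background arrays (0.0502), and that of the amino acid list with a floor of 100 (0.0967). Phenylpropanoid genes passing numbered 0 higher without outer integument array 1 or 2, and jasmonate genes passing numbered 0 lower without outer integument array 2. Maturation genes passing numbered 8 lower without outer integument array 2, and 1 higher without outer integument array 1, and early flavonoid genes passing numbered 3 lower without outer integument array 1 and 2 lower without outer integument array 2, and 0 higher without outer integument array 1, and aquaporins passing numbered 1 lower without outer integument array 1 and 0 lower without outer integument array 2. In all, 7038 of 31955 probe sets passed, 3729 higher and 3309 lower. The count was 3868 without outer integument array 1, the array with the higher background, and 4061 without the 3 high-background arrays.

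**Figure D4:**
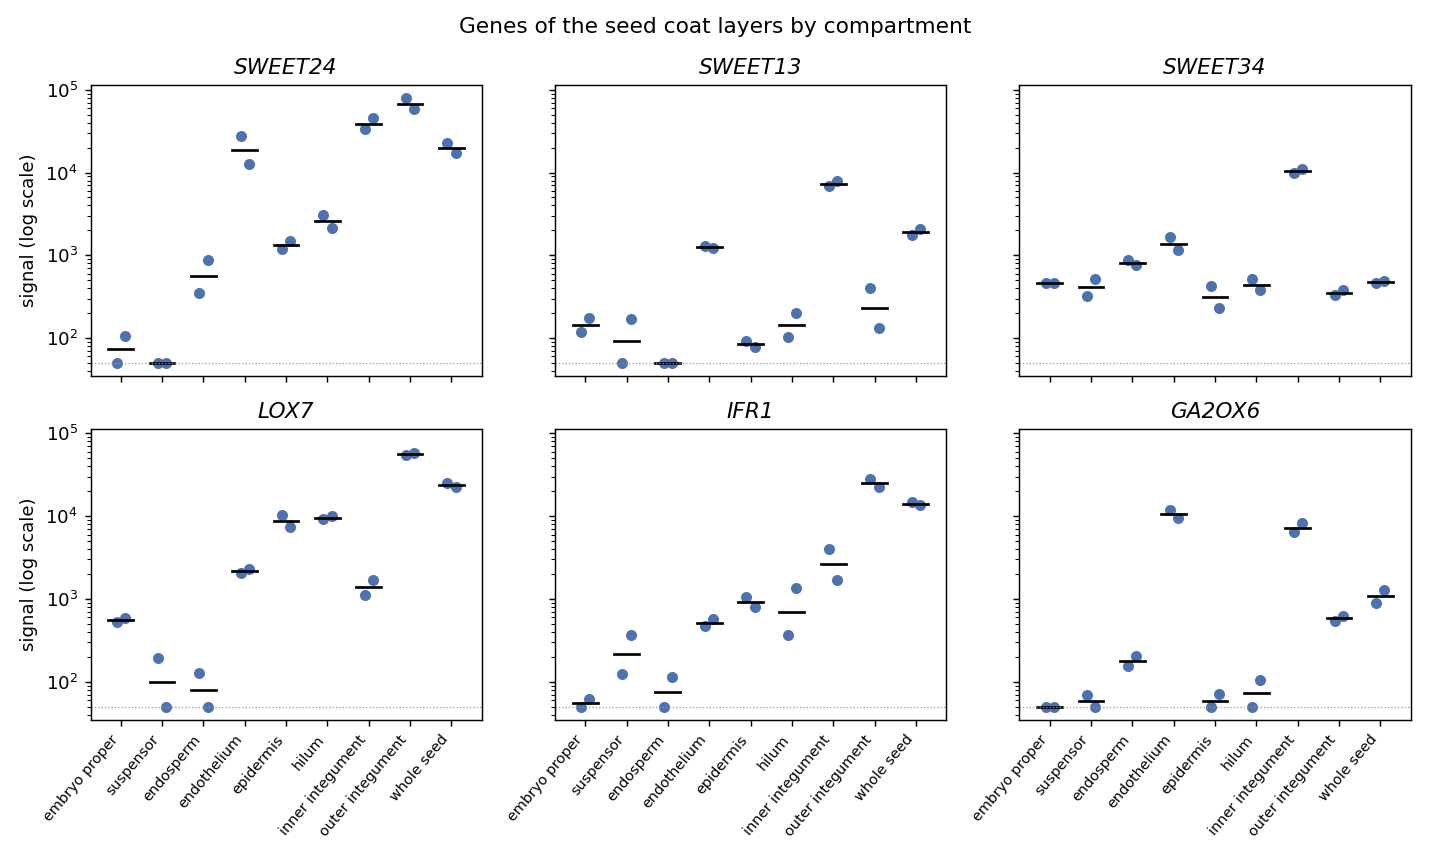
Signals (log scale) of 6 genes of the seed coat layers in the 9 groups, where each point is an array (values under 50 are drawn at 50), each black line is the geometric mean of 2 arrays and the dotted line is the floor of 50. SWEET24 and LOX7 have their highest means in outer integument (67566 and 56159), SWEET34 in inner integument (10499) and GA2OX6 in endothelium (10603).

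The embryo was compared with the seed coat by setting the mean of embryo proper and suspensor against the mean of the 5 seed coat compartments (4 arrays against 10). This contrast sets tissue of the new plant against tissue of the mother. P89 was 261-fold (log2 fold 8.03 ± 0.25 SE) higher in the embryo, PM12 114-fold (log2 fold 6.83 ± 0.29 SE) and SGR, of the stay-green family that acts in chlorophyll breakdown, 99.8-fold (log2 fold 6.64 ± 0.25 SE). MP2 had all seed coat arrays under the floor and was at least 87.9-fold higher. The other named rises were PARP3 (83.0-fold), SC-04 (73.8-fold), IF7MaT (73.0-fold), PM29 (66.3-fold), AT133 (65.8-fold), PM34 (61.1-fold), UGT78K1 (54.4-fold) and PM3 (50.04-fold). SWEET24 was 184-fold (log2 fold -7.52 ± 0.25 SE) lower in the embryo, and the MADS-box factors AGL1L, MADS28 and SEP1 were 129-fold, 65.4-fold and 50.3-fold lower. LOX7 (28.9-fold), DFR1 (24.8-fold), MYB73 (22.1-fold), GS-2 (16.3-fold) and LOX1.4 (15.6-fold) were lower too. The same held for LOX9, 117-fold without suspensor array 1 and 29.8-fold without array 2, PIP2-8, 42.6-fold without suspensor array 1 and 15.9-fold without array 2, and MYB172, 33.4-fold without suspensor array 1 and 9.71-fold without array 2, which with all arrays fell 59.1-fold, 26.03-fold and 18.01-fold.

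Of 29 maturation genes, compared between embryo and seed coat, 25 were higher, 1 lower and 3 neither (adjusted p = 4.8e-13, and 0.0149 with an estimated correlation), and the call held with the estimated correlation. The mean of the embryo joins unlike parts. PM25, 43.6-fold higher, had a signal of 38531 in suspensor and 184 in embryo proper, and PM32 had 30980.5 and 77.8, the latter within its range in the seed coat (53.5 to 80.4). Against the other 7 compartments, 26 maturation genes were higher in suspensor and 9 in embryo proper. Of 9 genes of plastid fatty acid synthesis, 5 were higher, 0 lower and 4 neither (adjusted p = 0.00976, and 0.314 with an estimated correlation), ACCB-2 by 4.29-fold and SAD2 by 3.25-fold. Of 6 MADS-box factors, 0 were higher, 5 lower and 1 neither (adjusted p = 3.95e-05, and 0.108 with an estimated correlation). Of 6 proanthocyanidin and anthocyanin genes, 1 was higher, 5 lower and 0 neither (adjusted p = 0.0361, and 0.283 with an estimated correlation), ANS2 by 17.8-fold and ANR1 by 12.7-fold, whereas UGT78K1, an anthocyanidin glucosyltransferase, was 54.4-fold higher in the embryo. The proanthocyanidin list lost its call (adjusted p in parentheses) without the 3 high-background arrays (0.0535). In all, 9755 of 31955 probe sets passed, 4680 higher and 5075 lower.

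Neighbouring layers of the seed coat were compared pair by pair (2 arrays against 2). Between endothelium and inner integument, GER2, of the germin family, was 14.3-fold (log2 fold 3.83 ± 0.68 SE) higher in endothelium, the alternative oxidase AOX1 13.6-fold and SARK 13.4-fold. EN1, with both endothelium arrays under the floor, was at least 25.2-fold lower in endothelium, the vacuolar processing enzyme VPE2 10.1-fold and the beta-amylase BMY2 8.80-fold. Folds lower in endothelium that varied by more than 1.5 times with the array left out were those of EN1, 43.1-fold without inner integument array 1 and 14.8-fold without array 2, GST3, 45.6-fold without inner integument array 1 and 12.6-fold without array 2 (23.93-fold with both), and MYB73, 20.3-fold without endothelium array 1 and 7.13-fold without array 2 (12.01-fold with both). ACS1 was 15.1-fold higher in endothelium, 5.45-fold without inner integument array 1 and 41.9-fold without array 2, and did not pass without endothelium array 1 (adjusted p = 0.163), endothelium array 2 (adjusted p = 0.0604) or inner integument array 1 (adjusted p = 0.318). ACS1 also did not pass with a floor of 100 (adjusted p = 0.0523), without a floor (0.0732), without the filter (0.104) or without the variance trend (0.0568). H4 was 11.3-fold higher and did not pass without endothelium array 1 (adjusted p = 0.0523) or inner integument array 1 (adjusted p = 0.0988), nor without a floor (adjusted p = 0.0704), the filter (0.0532) or the 3 high-background arrays (0.0904). Of 8 genes of sugar transport and cleavage, 0 were higher, 3 lower and 5 neither (adjusted p = 0.00439, and 0.397 with an estimated correlation), and 0 higher and 6 lower when adjusted over the list alone, SWEET34 by 7.57-fold and SWEET13 by 5.87-fold. Of 5 ribosomal proteins, 4 were higher, 0 lower and 1 neither (adjusted p = 0.00227, and 0.173 with an estimated correlation), RPL2 by 2.32-fold. Of 8 genes of proteases and cell death, 0 were higher, 2 lower and 6 neither (adjusted p = 0.0364, and 0.283 with an estimated correlation). The pair that passed was VPE2 and the cysteine protease CYSP1, and the call of the list was lost (adjusted p in parentheses) under quantile normalization (0.0863), with a floor of 100 (0.0596) and without the 3 high-background arrays (0.0584). CYSP1 was 8.79-fold lower (16.2-fold without inner integument array 1 and 4.76-fold without array 2). In all, 4195 of 31955 probe sets passed, 2178 higher and 2017 lower. Without endothelium array 1, endothelium array 2 or inner integument array 1 the counts were 2745, 2693 and 2318, and without the 3 high-background arrays 2452.

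Between inner and outer integument, NOD33 was 63.6-fold (log2 fold 5.99 ± 0.50 SE) higher in inner integument, AUX22 49.999-fold (log2 fold 5.64 ± 0.29 SE), and NAC14 49.3-fold higher. WRKY54, with both outer integument arrays under the floor, was at least 52.6-fold higher. N6L was 70.9-fold higher (159-fold without outer integument array 1 and 31.7-fold without array 2). CKX3 was 67.8-fold (log2 fold -6.08 ± 0.41 SE) lower in inner integument, the cytochrome P450 gene CYP72A67 51.99-fold and LOX7 40.8-fold. PRX2B, a peroxidase, was 33.5-fold lower (77.5-fold without inner integument array 1 and 14.4-fold without array 2) and SGT2 30.4-fold (19.7-fold without inner integument array 1 and 46.8-fold without array 2). Of 15 jasmonate and lipoxygenase genes, 0 were higher, 11 lower and 4 neither (adjusted p = 0.000212, and 0.0596 with an estimated correlation), VLXB by 7.86-fold. Of 9 phenylpropanoid and lignin genes, 4 were higher, 0 lower and 5 neither (adjusted p = 0.0272, and 0.173 with an estimated correlation), 4CL1 by 47.3-fold and C4H by 12.6-fold. Of 8 genes of sugar transport and cleavage, 4 were higher, 0 lower and 4 neither (adjusted p = 0.0391, and 0.434 with an estimated correlation), and 4 higher and 0 lower when adjusted over the list alone, SWEET34 by 29.5-fold. The call of the sugar list was lost (adjusted p in parentheses) with a floor of 25 (0.0625), without a floor (0.0770), with the captured arrays alone (0.05003) and without the 3 high-background arrays (0.0704). Sugar genes passing numbered 2 higher without inner integument array 1 or outer integument array 2. In all, 6582 of 31955 probe sets passed, 3095 higher and 3487 lower, and 3447 passed without the 3 high-background arrays.

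Between epidermis and outer integument, SSH2 was 87.1-fold (log2 fold 6.45 ± 0.52 SE) higher in epidermis, MYB11 59.7-fold (log2 fold 5.90 ± 0.50 SE) and ANR1 44.3-fold (log2 fold 5.47 ± 0.44 SE). MYB172 and ANS2 were 39.6-fold and 37.6-fold higher. Rsv4 was 63.9-fold (log2 fold -5.998 ± 0.45 SE) lower in epidermis, N-26 55.3-fold and SWEET24 50.7-fold. SSTP-1 was 70.9-fold lower (43.3-fold without outer integument array 1 and 116-fold without array 2) and MYB138 61.9-fold (163-fold without epidermis array 1 and 23.6-fold without array 2). Of 6 proanthocyanidin and anthocyanin genes, 4 were higher, 0 lower and 2 neither (adjusted p = 4.01e-05, and 0.0944 with an estimated correlation), DFR1 by 37.3-fold. Of 9 early flavonoid genes, 5 were higher, 0 lower and 4 neither (adjusted p = 0.000381, and 0.113 with an estimated correlation), CHI2-A by 25.7-fold and CHI4A by 20.4-fold. Of 15 jasmonate and lipoxygenase genes, 0 were higher, 8 lower and 7 neither (adjusted p = 0.000260, and 0.0596 with an estimated correlation), VLXC by 20.4-fold and VLXB by 4.58-fold. Early flavonoid genes passing numbered 1 lower without epidermis array 2. In all, 4487 of 31955 probe sets passed, 2184 higher and 2303 lower, and 2575 passed without the 3 high-background arrays.

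Whole seed was compared with the mean of the 8 captured compartments (2 arrays against 16). The contrast takes the mean of log2 signals, so a gene confined to 1 or a few compartments comes out higher in any mixture of them. Of 3775 probe sets that passed and were higher, 2450 did not lie above the mean of their highest compartment. SALI5-4A was 77.02-fold (log2 fold 6.27 ± 0.42 SE) higher in whole seed, BZIP16 30.1-fold (log2 fold 4.91 ± 0.40 SE) and GS1GAMMA2, a glutamine synthetase, 27.8-fold (log2 fold 4.80 ± 0.60 SE). The peroxidase Ep was 25.6-fold higher and MIPS4, a myo-inositol phosphate synthase, 17.4-fold. BZIP94 was 5.05-fold (log2 fold -2.34 ± 0.29 SE) lower and ADR12 4.15-fold. GPPS (3.21-fold), IFR (2.52-fold) and MYB12A (2.52-fold) were lower as well but did not pass without whole seed array 1 (adjusted p = 0.138, 0.178 and 0.0690) or array 2 (adjusted p = 0.0577, 0.258 and 0.168). With a floor of 100, GPPS and IFR did not pass (adjusted p = 0.0872 and 0.0684), and IFR did not under quantile normalization (0.0578), without a floor (0.0501) or without the filter (0.0506). The captured RNA and the whole seed RNA were extracted with different reagents, so dissection, extraction and tissue cannot be separated in this contrast.

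Higher and lower in whole seed are relative to that mean of log2 signals, and for genes of few compartments higher can follow from the contrast alone. Of 18 genes of gibberellin turnover and response in whole seed, 11 were higher, 1 lower and 6 neither (adjusted p = 0.00102, and 0.356 with an estimated correlation), and 13 higher and 1 lower when adjusted over the list alone, GASA29 by 14.9-fold and GASA6 by 12.3-fold. Of 15 jasmonate and lipoxygenase genes, 10 were higher, 2 lower and 3 neither (adjusted p = 0.00174, and 0.0944 with an estimated correlation), LOX7 by 14.2-fold and VLXC by 12.7-fold. Of 6 proanthocyanidin and anthocyanin genes, 4 were higher, 0 lower and 2 neither (adjusted p = 0.000777, and 0.128 with an estimated correlation), ANR1 by 24.7-fold and DFR1 by 20.5-fold. Early flavonoid genes in whole seed numbered 9, of which 4 were higher, 0 lower and 5 neither (adjusted p = 0.0359, and 0.278 with an estimated correlation), CHI2-A by 5.81-fold. Of 5 cell wall proteins, 4 were higher, 0 lower and 1 neither (adjusted p = 0.00166, and 0.169 with an estimated correlation), SBPRP by 13.8-fold and PRP3 by 8.79-fold. Of 18 genes of amino acid and nitrogen use, 9 were higher, 1 lower and 8 neither (adjusted p = 0.0210, and 0.274 with an estimated correlation), AS2 by 11.6-fold and NRT1-3 by 4.88-fold. MADS-box factors in whole seed counted 6, of which 4 were higher, 0 lower and 2 neither (adjusted p = 0.0124, and 0.260 with an estimated correlation), NMH7 by 10.4-fold. Of 29 maturation genes, 2 were higher, 6 lower and 21 neither (adjusted p = 0.00398, and 0.169 with an estimated correlation). Of 45 WRKY factors, 2 were higher, 9 lower and 34 neither (adjusted p = 0.0347, and 0.523 with an estimated correlation), and 2 higher and 9 lower when adjusted over the list alone, WRKY37 by 2.53-fold (adjusted p = 0.0715 without whole seed array 1), whereas WRKY29 was 4.10-fold higher. Of 18 NAC factors, 0 were higher, 3 lower and 15 neither (adjusted p = 0.0488, and 0.356 with an estimated correlation), and 0 higher and 3 lower when adjusted over the list alone. The WRKY list lost its call (adjusted p in parentheses) with a floor of 25 (0.0901), without a floor (0.141), with the filter at 300 (0.0701) and with all probe sets of a gene (0.0700). That of the NAC list was lost with a floor of 25 (0.121), without a floor (0.174), without the filter (0.0683), without the 3 high-background arrays (0.0552) and with all probe sets of a gene (0.0700), that of the early flavonoid list with a floor of 100 (0.0734) and with the filter at 300 (0.0606) and that of the maturation list with all probe sets of a gene (0.0579). WRKY factors passing numbered 0 lower without whole seed array 1 and 2 lower without whole seed array 2, and 1 higher without embryo proper array 1 or 2, endosperm array 1 or 2, epidermis array 2, hilum array 2, inner integument array 2, outer integument array 1 or 2 or whole seed array 1 or 2. For the other lists, NAC factors passing numbered 0 lower without whole seed array 1, maturation genes passing numbered 2 lower without whole seed array 1 and 1 lower without whole seed array 2, and 1 higher without embryo proper array 1, endosperm array 2 or whole seed array 1 or 2, jasmonate genes passing numbered 1 lower without whole seed array 1 and 0 lower without whole seed array 2, gibberellin genes passing numbered 0 lower without whole seed array 1 or 2, and amino acid genes passing numbered 0 lower without whole seed array 1 or 2. In all, 6191 of 31955 probe sets passed, 3775 higher and 2416 lower. Leaving out whole seed array 1 gave 2651 and leaving out array 2 gave 2416.

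Storage globulins and albumins, the genes of seed protein reserves, had 9 measured members and no call as a list in any of the 14 contrasts (adjusted p from 0.444 to 0.919). A1 had a signal of 4629.8 in embryo proper and 374 in suspensor, 12.4-fold higher in the former, a call lost without a floor (adjusted p = 0.0841). The glycinin gene GY1 had 79.1 and 133, and at most 108 in any other group. Against the other 7 compartments the list had 2 higher and 0 lower in embryo proper and 1 higher and 0 lower in suspensor. In embryo proper, SBP2 lost its call (adjusted p in parentheses) with a floor of 25 (0.0598), without a floor (0.135), without the 3 high-background arrays (0.0562), without embryo proper array 1 (0.103) and without embryo proper array 2 (0.204), which left 1 higher without either embryo proper array. In suspensor, storage genes passing numbered 0 higher without suspensor array 2, 3 higher without hilum array 2 or outer integument array 1 and 2 higher without inner integument array 1 or whole seed array 1 or 2. SBP2 was 3.83-fold higher there (5.79-fold without suspensor array 1 and 2.53-fold without array 2, the latter with adjusted p = 0.0688). Gibberellin synthesis had 1 measured gene, GA20OX3, which was 11.7-fold (log2 fold 3.54 ± 0.41 SE) higher in embryo proper (adjusted p = 2.95e-06). It was also 9.01-fold higher there than in suspensor (5.20-fold without suspensor array 1 and 15.6-fold without array 2). Cuticle genes had 3 measured members, too few to test as a list, of which CYP77A3 was 8.35-fold (log2 fold 3.06 ± 0.47 SE) higher in suspensor. The lipid transfer gene HPS was 2.60-fold higher in endosperm, and no longer passed without endosperm array 2 (adjusted p = 0.179) or without a floor (adjusted p = 0.0671). CYP94D24 was 2.43-fold higher in outer integument, and no longer passed without outer integument array 1 (adjusted p = 0.318) or array 2 (adjusted p = 0.0614), nor with a floor of 100 (adjusted p = 0.132), without a floor (0.112), without the filter (0.0513) or without the 3 high-background arrays (0.155). The 7 reference genes had no call as a list in any contrast (adjusted p from 0.265 to 0.993), but members differed between compartments, with 3 higher and 1 lower in embryo proper, 3 higher and 2 lower in suspensor, 3 higher and 3 lower in endosperm and 3 higher and 2 lower in inner integument. These counts varied with the array left out. In embryo proper, those passing numbered 0 lower without embryo proper array 1 or 2, and 1 higher without embryo proper array 1 or 2. In suspensor, those passing numbered 1 lower without suspensor array 2, and 1 higher without suspensor array 1, in endosperm, those passing numbered 0 higher without endosperm array 1 and 1 higher without endosperm array 2, and in inner integument, those passing numbered 1 higher without inner integument array 2. The elongation factor gene TEFS1 was 1.84-fold lower in inner than in outer integument, but under quantile normalization it was higher by 0.08 on the log2 scale (adjusted p = 0.680). The call was also lost without the filter (0.0860), without the variance trend (0.103), without the 3 high-background arrays (0.269), without inner integument array 1 (0.0772), without inner integument array 2 (0.110) and without outer integument array 1 (0.249).

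Quantile normalization moved the median log2 fold over all tested probe sets by more than 0.1 in 4 contrasts. It went from -0.099 to 0.034 in endosperm, from -0.124 to -0.011 in endothelium, from 0.083 to -0.048 in hilum, and from -0.108 to 0 in endothelium against inner integument. TEFS1 in inner against outer integument was the gene whose direction turned, among the followed gene results that passed without it.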

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

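The tests of a deviating suspensor array, of single whole seed arrays and of the GAPDH ratio were chosen after the results were seen. The array also carries probe sets for 2 other organisms, which the comparisons do not use. Of 15820 probe sets for the oomycete Phytophthora sojae, 109 (0.689%) had a signal of at least 100 on all 18 arrays and 3 had at least 1000, with a highest median over arrays of 63322. Of 7530 for the nematode Heterodera glycines, 94 (1.25%) had at least 100 on all arrays and 1 at least 1000, with a highest median of 1896. There were no arrays without seed RNA to compare with. Whether these signals come from binding of soybean transcripts or from the organisms was not tested.

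Maturation genes had higher signals in suspensor than in embryo proper, 25 of 29 by their means and 21 past the threshold. Mixed-in RNA of maturing embryos would bring storage protein transcripts, but the median fold of the 9 storage genes, suspensor over embryo proper, was 1 against 15.0 for the maturation genes. That argument is limited, since most storage genes had low signals in both, and A1, with a high signal, was lower in suspensor. A scaling difference is argued against by the reference genes, whose median absolute log2 shift was 0.819 against 3.91 for the maturation genes, and a single deviating suspensor array by the median log2 difference of the 29 genes to embryo proper, 3.93 on 1 suspensor array and 3.94 on the other. An earlier start of maturation in suspensor may be a hypothesis for these values. The hypothesis was not tested, and arrays of both parts from earlier and later stages would decide it.

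In whole seed, 157 probe sets were higher than in each of the 8 compartments, 61 of them at least 4-fold over the highest, and 135 were lower than in each. Among the 61 were BZIP16 (12.7-fold), SALI5-4A (12.01-fold) and SEOF (10.6-fold). A plain mixture of the compartments cannot exceed its highest part. The 61 are over the 10 that noise was allowed in a mixture, though under the 100 set in advance to exclude one. Read array by array, 33 probe sets had both whole seed arrays at least 4-fold above the highest of the 16 captured arrays, which argues against a plain mixture as the source of these. The GAPDH ratio of 3-prime to middle signal was at most 35.4 on the whole seed arrays and at least 71.5 on the captures. The actin ratio of 3-prime to 5-prime signal, 55.8 and 91.8 on whole seed, lay within the captures (31.8 to 349), as did that of ubiquitin (2.29 and 4.56, within 0.0526 to 5.8). RNA extraction differs between whole seed and captures and cannot be told apart from tissue left uncaptured, which was not tested.

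In hilum, 56.5% of passing probe sets were higher than in the other compartments. With the filter at 300 the share was 51.0%, at or under the 52% set for a higher array background. The median log2 shift of other-organism probe sets in hilum was 0.36, beside 0.36 for dim soybean probe sets, which leaves open how much of the excess is background. A higher background may account for the excess of higher calls. Whether hilum cells also transcribe more genes was not tested.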

How the results depend on the processing

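The alternative without the 3 high-background arrays was chosen after the data were seen. Of 660 gene results, 551 kept direction and side of the threshold in each alternative that gave them a value, single arrays left out included. Values were had for 584 with the filter at 300 (0 calls lost), 599 with the captured arrays alone (4 lost) and 654 under quantile normalization (9 lost). Of all 660, 30 calls were lost without the 3 high-background arrays, 25 without a floor and 21 without the filter. TEFS1 in inner against outer integument reversed to 0.0818 on the log2 scale under quantile normalization, and the cause was not tested. Replicate numbers did not pair the samples: over 36 pairs of groups the differences between replicates had a median correlation of 0.00962, and with a replicate block 2 gene calls were lost. Of 108 list results, 68 lost their call with the estimated correlation, and 11 without the 3 high-background arrays. The lists tested in advance gave 11 calls, but 0 with the estimated correlation, 7 with the captured arrays alone (where 3 of the 11, in whole seed, have no test) and 20 with all probe sets of a gene. For the symbol lists, 61 calls became 4 with the estimated correlation and 129 with all probe sets, since probe sets of 1 gene are then counted as separate members. Without 1 array, passing probe sets ranged over 3964 to 7877 in embryo proper, 5985 to 8799 in suspensor, 5595 to 10066 in endosperm, 3083 to 5873 in endothelium, 2277 to 4862 in epidermis, 3522 to 7146 in hilum, 5744 to 9235 in inner integument, 3868 to 7361 in outer integument, each against the other 7. They ranged over 5267 to 7993 for embryo proper against suspensor, 7406 to 10044 for embryo against seed coat, 2318 to 4503 for endothelium against inner integument, 4463 to 6923 for inner against outer integument, 3162 to 4764 for epidermis against outer integument and 2416 to 6581 for whole seed. Probe sets highest in a compartment ranged over 303 to 494 in embryo proper, 667 to 808 in suspensor, 297 to 603 in endosperm, 69 to 142 in endothelium, 64 to 120 in epidermis, 150 to 265 in hilum, 248 to 458 in inner integument, 252 to 464 in outer integument. Without the 3 high-background arrays, 2208 passed in epidermis, 5875 in inner integument, 4061 in outer integument, 2452 for endothelium against inner integument, 3447 for inner against outer integument and 2575 for epidermis against outer integument. The highest-in counts were then 75 in endothelium, 65 in epidermis, 240 in inner integument and 215 in outer integument. Probe sets highest in hilum numbered 160 with a floor of 25, 463 with a floor of 100 and 97 without one. Without a floor there were 325 in embryo proper, 52 in epidermis and 286 in outer integument, and the cause was not tested. Signals near the floor limit what the arrays show of genes with little RNA.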

Other observations

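The values in the first 2 paragraphs here were picked after they were seen, and the tests of other splits were planned. Of the isoflavonoid genes, the isoflavone synthase gene IFS2 had a signal of 2747 in suspensor and at most 83.7 in any other group, and the chalcone reductase gene CHR5 had 3227 there and at most 67.9 elsewhere. HIDH was highest in hilum (17873), and IFR1 in outer integument (24941). The aquaporin gene PIP1-1 had 16804 in suspensor and 3882 in hilum, and PIP2-4 had 59935 in epidermis and 43783 in hilum. These are geometric means of 2 arrays.

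The embryo regulator gene LEC1-A had signals of 4853 in embryo proper, 6776 in suspensor and 2296 in endosperm, and at most 256 in the 5 seed coat compartments. WRI1B, of the family that regulates oil synthesis, was highest in embryo proper (3144). The desaturase gene FAD3C had 19329 in inner integument, 11623 in endothelium and 11083 in endosperm. The starch synthase gene GBSSIa had 16129.5 in embryo proper, 17211 in suspensor and 10937 in outer integument, and at most 2351 in the other captures. Among sieve element occlusion genes, SEOE was highest in inner integument (3387), and SEOA had 1029 in outer integument. XTH1, of cell wall remodelling, had 46436 in outer integument.

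For embryo against seed coat, the 14 arrays were also divided at random into 4 and 10. In a fit with 2 groups, 2 of 100 such splits, the real one included, gave as many passing probe sets (real 2034, highest other 2354). These splits part the 2 arrays of a compartment and so do not test how compartments are grouped. Of the 21 splits of whole compartments into 2 and 5, 2 gave as many (real 9755, highest other 10268, endothelium with inner integument). All part unlike tissues, so chance was not tested.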
